A study of Mus musculus with 4 samples.

How the data were processed

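E5hmC-seq libraries of Lin– bone marrow cells from 2-month-old mice were compared between Tet3F/F controls (n = 2) and Tie2+/cre; Tet3F/F mice (Tet3_cKO, n = 2). Per the labels the authors used 200 ng of DNA per library and the NEBNext E5hmC-seq kit, and list Trim Galore 0.6.7, Bismark 0.23.1, SAMtools, ChIPseeker and the mm10 build; the role of each tool is not stated. The deposited values give, for each strand of each CpG, the level as a fraction of calls that stayed unconverted. Beside it, the deposited values give the coverage in counts of calls. Neither was normalised. The product of fraction and coverage was checked to be whole, within a deviation of at most 0.000505, and taken as the number of unconverted calls.

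The strands of each CpG were summed. Total calls per library were 1184798689, 925836091, 1009106472 and 982504100. A CpG was used when covered at least 3 times in every library. Control replicate 2 has values on chromosomes 1 to 18 only and on chromosome 18 up to position 82683106, so chromosomes 19, X, Y and M were left out of the comparisons. The 95% intervals of single-library levels are Wilson intervals and cover counting error only. Genes came from a GRCm38 gene table with start and end but without strand or exons, so promoters, UTRs, exons and introns were not placed. In their stead, gene ends (1 kb either side of both ends), gene bodies and CpG density in 1 kb bins were used.

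Levels of the whole genome and of each class were compared by an exact permutation test of the library values. Gene bodies (at least 10 CpGs and 200 calls in every library), gene ends (5 CpGs and 50 calls) and 5 kb windows (5 CpGs and 100 calls) were tested with a quasi-binomial logistic model. Its dispersion was squeezed across regions with limma 3.58.1 in R 4.3.3, and its F-test was adjusted by Benjamini-Hochberg with a threshold of 0.05. For windows as measured and with library centring, the squeezing made the dispersion fully shared along the trend; with the background removed the prior degrees of freedom were 63.9. Lists of genes were tested with limma camera with a preset correlation of 0.01 and with an estimated correlation. The genes named are those past the threshold with both Tet3_cKO libraries on one side of both controls, up to 10 per direction by largest change. Where fewer passed, those with the smallest p up to 5 per direction were added as not past the threshold. The rule also takes the 5 gene bodies highest in the controls, the TET and DNMT enzymes and the members of smallest p of each list. Of these, the examples printed are part. For gene ends and windows, 5 per direction were taken. Bcl11b, Gata3, Cd3g, Tbx21 and Zeb2 were named after their values were seen.

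Alternatives were the coverage minimum (1, 10), CpGs above a mean level of 80%, each library left out, the replicate number as a block, library centring (each library's genome-wide log odds as an offset), edgeR 4.0.16, limma on log2 odds with 0.5 added, other region sizes and other minimums. Chosen after the data were seen were additive centring, removal of an additive background (in each CpG density class, a library's level above the lowest library was subtracted), the removal of sites marked CpGx, gene ends, the search for uncovered runs and the combinations of centring or background removal with a left-out library. The gene body and window tests were tested on simulated counts with 200 changed regions per size of change, real calls and the fitted spread. Without library shifts, the gene body test recovered 74% of those changed 2 times. With each library's genome-wide shift simulated as a constant offset in log odds, it recovered 0%, and 72% with library centring. Centring used the same offsets, so that recovery was largely given in advance. It does not cover a shift whose log odds vary with the level. Of the gene bodies called without library shifts, 8.47% were unchanged. Levels and tables were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures in matplotlib 3.10.9. The lambda and T4 spike-in DNA was not analysed here, so the share of cytosines that failed to convert was not measured.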

Results

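The data are base-resolution maps of 5-hydroxymethylcytosine (5hmC) in lineage-negative (Lin–) bone marrow cells, as the sample labels name them, a fraction rich in blood stem and progenitor cells; the extraction protocol in the labels names NE cells instead. Control libraries came from Tet3F/F mice (n = 2) and Tet3_cKO libraries from Tie2+/cre; Tet3F/F mice (n = 2), in which Cre under the Tie2 promoter is active in endothelial and blood-forming cells. TET3 is an enzyme that oxidises 5-methylcytosine to 5hmC. In the E5hmC-seq assay a cytosine that stays unconverted is read as 5hmC, so the level of a region is the share of its calls at CpGs that stayed unconverted. The libraries held 1184798689 calls (control replicate 1), 925836091 (control replicate 2), 1009106472 (Tet3_cKO replicate 1) and 982504100 (Tet3_cKO replicate 2), with a median coverage per CpG of 58, 48, 49 and 47. In control replicate 1, 11.2% of CpGs had over 90% of their calls on 1 strand, against 1.23% to 1.28% in the other 3 libraries. The values of control replicate 2 covered chromosomes 1 to 17 and chromosome 18 up to position 82683106, where the other libraries reach 90601969, so the comparisons were made there, at 19044325 CpGs covered at least 3 times in every library. Positions are in the mm10 build.

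The first comparison asked whether the Tet3 gene itself was altered in the Tet3_cKO libraries. A segment of 7 CpGs inside Tet3, at chromosome 6 from 83385908 to 83386003, was nearly uncovered in both Tet3_cKO libraries. Its coverage was 1.75% of the library median in Tet3_cKO replicate 1 (6 calls) and 0.304% in Tet3_cKO replicate 2 (1 call). The same CpGs stood at 94.3% in control replicate 1 (383 calls) and 60.1% in control replicate 2 (202 calls). The ratio of the Tet3_cKO mean to the control mean was 0.0133 (0.00394 without Tet3_cKO replicate 1 and 0.0227 without Tet3_cKO replicate 2). The nearest CpGs on either side, at 83385690 and 83386509, were covered in all 4 libraries, and the rest of the gene (83362373 to 83457208) stood at 83.0% and 82.1% in the Tet3_cKO libraries against 95.7% and 78.8% in the controls. The segment was found by searching the gene for runs of at least 5 CpGs below 10% of the library median in both Tet3_cKO libraries and above 30% in both controls, a criterion chosen after the coverage was seen. The same criterion held for 30 runs across chromosomes 1 to 18. No test was planned for this comparison, and the gene table used here gives no exons, so the segment was not placed on an exon.

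**Figure D1:**
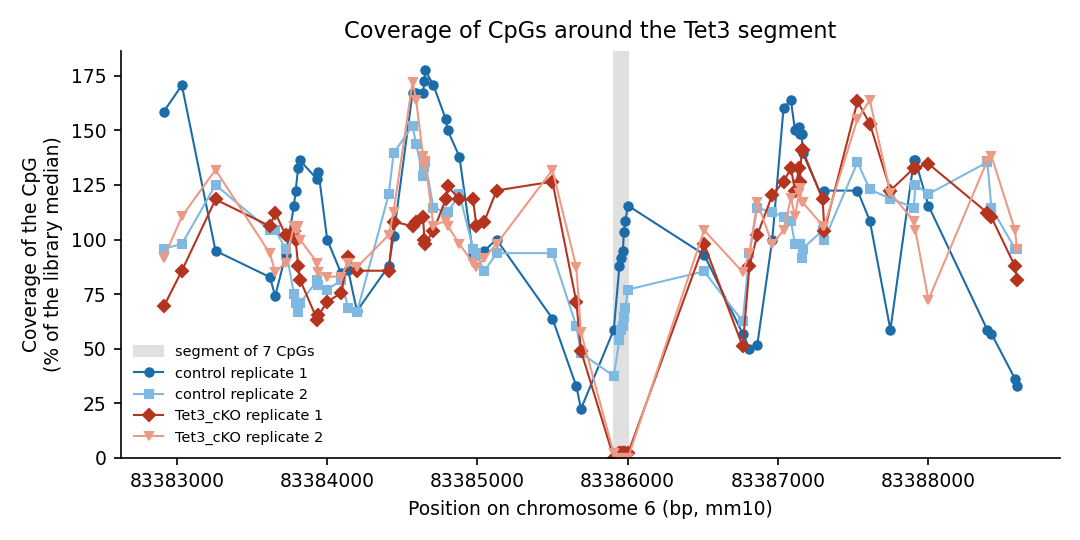
Coverage of each CpG (percent of the library's median CpG coverage) against its position on chromosome 6 around the Tet3 segment, 1 line per library. Within the shaded segment of 7 CpGs both Tet3_cKO libraries fall to 1.75% and 0.304% of the library median, while the controls stand at 94.3% and 60.1%.

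The second comparison asked whether loss of TET3 changed the amount of 5hmC across the genome. The autosomal 5hmC level was 1.19% ± 0.0599 (SD, n = 2) in the Tet3_cKO libraries and 1.64% ± 0.568 (SD, n = 2) in the controls. The controls lay far apart: control replicate 1 stood at 2.04% and control replicate 2 at 1.24%, next to 1.15% and 1.23% in the Tet3_cKO libraries. The difference of -0.446 percentage points was smaller than the SD of the controls, with an exact two-sided permutation p = 0.333, the smallest that 2 libraries against 2 can give. Against control replicate 2 alone the difference was -0.0447 points and against control replicate 1 alone -0.848, so 1 library decided its size. The Wilson 95% interval of control replicate 2 ran from 1.234% to 1.236%. Such intervals cover counting error only, and the spread between the control libraries was far wider.

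Gene bodies carried more 5hmC than the space between genes in every library. Protein-coding gene bodies stood at 1.37% ± 0.0735 (SD, n = 2) in Tet3_cKO and 1.80% ± 0.529 in the controls, and CpGs outside annotated genes at 0.958% and 1.02% in the Tet3_cKO libraries and 1.88% and 1.03% in the controls. CpG-dense sequence, with over 30 CpGs per kb, held the least, with 0.752% ± 0.0306 in Tet3_cKO and 0.904% ± 0.183 in the controls. Gene ends, taken as 1 kb either side of both ends of a protein-coding gene, stood at 1.11% ± 0.0583 and 1.29% ± 0.209. Other annotated genes stood at 1.18% ± 0.0614 and 1.59% ± 0.554. Bins of 1 to 10 CpGs per kb stood at 1.04% ± 0.0523 and 1.55% ± 0.649, and bins of 11 to 30 CpGs per kb at 1.43% ± 0.0751 and 1.86% ± 0.547. None of the 7 classes passed an exact permutation test (adjusted p from 0.583 to 0.667), which 2 libraries against 2 cannot pass.

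**Figure D2:**
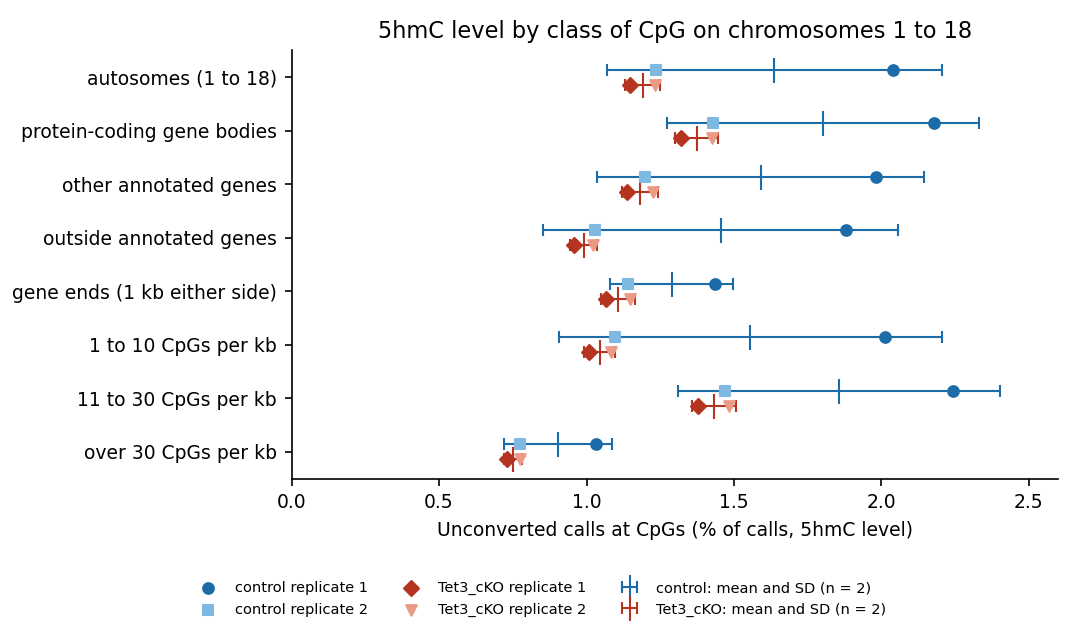
5hmC level (percent of calls at CpGs that stayed unconverted) by class of CpG, with each library as a point and each genotype's mean and SD (n = 2) as a bar. Control replicate 1 lies above the other 3 libraries in every class, and the autosomal level of control replicate 2 (1.24%) lies next to those of Tet3_cKO (1.15% and 1.23%).

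The third comparison asked which genes gained or lost 5hmC. H3c13, which encodes a histone H3, rose from 0.282% ± 0.288 (SD, n = 2) in the controls to 2.97% ± 2.20 in Tet3_cKO, a log2 odds change of 3.06 ± 0.75 (SE; quasi-binomial model with limma-squeezed dispersion, adjusted p = 0.0110). Olfr323, an olfactory receptor gene, fell from 5.47% ± 1.58 to 1.06% ± 0.149, with a log2 odds change of -2.54 ± 0.56 (adjusted p = 0.000545). In each gene both Tet3_cKO libraries lay on one side of both controls. These were the only gene bodies of 18475 that passed, with 1231 at an unadjusted p under 0.05; edgeR called 3 and limma 17. Without control replicate 1 the count was 8, without control replicate 2 13342, and without either Tet3_cKO replicate 0 (quasi-binomial model with limma-squeezed dispersion; 48 and 62 at an unadjusted p under 0.05). Both Tet3_cKO libraries lay above both controls in 342 gene bodies and below both in 8752, where chance gives 16.7% each way for libraries of equal level; control replicate 1 stood at 2.04% against 1.15% to 1.24%, so its shift alone moves both counts. H3c13 lies at chromosome 3 from 96268654 to 96269155. Around it, between 77597385 and 128697655, 240 runs of CpGs were nearly uncovered in control replicate 1 and Tet3_cKO replicate 2 alone. Olfr323 lies at chromosome 11 from 58625073 to 58626044. Both genes belong to families of similar genes, where the placement of reads is uncertain. With an additive background removed neither passed (adjusted p = 0.287 for both, 0 of 18475 gene bodies called with the limma-squeezed dispersion and 1722 at an unadjusted p under 0.05). In counts simulated with a constant log odds shift per library, this test recovered 0% of gene bodies whose odds changed 1.5 or 2 times. Of those changed 3 times it recovered 6%.

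Genes that did not pass but were among those with the smallest p in each direction are given as values. The olfactory receptor gene Olfr1509 stood at 4.51% ± 0.181 (SD, n = 2) in the controls and 8.08% ± 0.499 in Tet3_cKO, 1110065P20Rik at 0.507% ± 0.119 and 1.86% ± 0.101, and Mab21l2 at 0.257% and 0.229% in the controls and 1.30% and 0.695% in Tet3_cKO. In the other direction, Olfr547 stood at 2.31% ± 0.744 and 0.102% ± 0.144, the testis histone gene H2bc1 at 1.27% ± 1.55 and 0.0771% ± 0.109, Ctxn1 at 1.46% ± 1.31 and 0.342% ± 0.154, and the linker histone gene H1f7 at 1.53% ± 0.946 and 0.310% ± 0.0820. The gene bodies with the most 5hmC in the controls were E030018B13Rik (8.78% ± 0.0110), Tyrobp (7.82% ± 1.28), Hus1b (7.48% ± 0.0823), Zbtb12 (6.97% ± 1.64) and Ccl24 (6.85% ± 0.0557). Tyrobp, an adaptor of myeloid and NK cell receptors, stood at 5.77% ± 0.586 in Tet3_cKO and Zbtb12 at 8.04% ± 0.552. None of these 5 passed.

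The genes of the methylation machinery did not pass the test. The Tet3 gene body stood at 2.92% ± 0.406 (SD, n = 2) in the controls and 2.73% ± 0.0587 in Tet3_cKO, Tet1 at 1.95% ± 0.451 and 1.69% ± 0.0889, and Tet2 at 2.63% ± 0.394 and 2.24% ± 0.169. The maintenance methyltransferase Dnmt1 stood at 2.23% ± 0.566 and 1.69% ± 0.0733. The de novo methyltransferases Dnmt3a and Dnmt3b stood at 2.82% ± 0.486 and 2.22% ± 0.0920, and at 1.87% ± 0.359 and 1.44% ± 0.169.

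At gene ends, 5hmC rose at 5 ends and fell at 10 of 38450 (adjusted p under the threshold of 0.05, quasi-binomial model; 4285 at an unadjusted p under 0.05; limma and edgeR called 0). The shared end of Arv1 and Ttc13, counted once for each gene, rose from 0.170% ± 0.135 (SD, n = 2) to 2.07% ± 1.28 (log2 odds change 3.92 ± 0.92 SE, limma-squeezed adjusted p = 7.61e-05). The lower end of Arhgap30 rose from 0.866% ± 0.113 to 5.19% ± 0.954 (2.68 ± 0.51, limma-squeezed adjusted p = 5.79e-05) and was the only end to pass with an additive background removed (adjusted p = 0.0406). The lower end of the oestrogen receptor gene Esr1 rose from 0.543% and 0.551% in the controls to 2.65% and 3.50% in Tet3_cKO, and the higher end of Supt3 from 2.40% ± 0.0908 to 6.22% ± 0.742. Both ends of Olfr323 fell, the lower from 4.65% ± 1.24 to 0.893% ± 0.183. These ends overlap and each holds the whole gene body, so they are not separate from its call. The lower end of the peptidase gene Thop1 fell as well, from 1.99% ± 0.256 to 0.284% ± 0.0549. The lower end of Zfp229 and the higher end of Srsf12 also fell, but there control replicate 1 alone stood high (3.66% and 5.25%, against 0.626% and 0.840% in control replicate 2). No gene end passed without control replicate 1, control replicate 2 or Tet3_cKO replicate 2 (0 of 38450 each with the limma-squeezed dispersion; 1924, 9408 and 1213 at an unadjusted p under 0.05), and 3 passed without Tet3_cKO replicate 1. With the same simulated constant shifts, the recovery at gene ends changed 3 times was 1.5%. Set against the other libraries, control replicate 1 with Tet3_cKO replicate 1 called 4 ends, and with Tet3_cKO replicate 2 it called 1.

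Of 461613 windows of 5 kb, 5hmC rose in 1 and fell in 49 by the quasi-binomial model, with 32476 at an unadjusted p under 0.05. By edgeR 57 were called and by limma 168. In the quasi-binomial model control replicate 1 with Tet3_cKO replicate 1, set against the other libraries, called 26 windows. With Tet3_cKO replicate 2 it called 19. The window that rose lies in Colec12, a scavenger receptor gene, at chromosome 18 from 9870001 to 9875000. Its level was 7.32% and 7.35% in the Tet3_cKO libraries and 3.46% and 0.467% in the controls, a log2 odds change of 2.14 ± 0.46 (SE, limma-squeezed adjusted p = 0.00968). No window was called higher by edgeR (0 of its 57) or without the sites marked CpGx (0 of 48 called with the limma-squeezed dispersion; 32768 at an unadjusted p under 0.05). Windows in Cytip (6.87% ± 0.258 in Tet3_cKO, 2.88% ± 0.534 in the controls; SD, n = 2), Ankrd13a (8.96% ± 0.497, 5.09% ± 0.452), Abtb2 (6.74% ± 0.337, 3.10% ± 0.191) and Wdfy1 (2.97% ± 0.571, 1.18% ± 0.208) did not pass as measured and passed with an additive background removed. In that fit control replicate 1 with Tet3_cKO replicate 1, set against the other libraries, called 69 windows higher. The real split called 44 higher, so passing there says little of genotype. As measured, windows that fell included 1 in Pkhd1 (0.632% ± 0.139 in Tet3_cKO, 5.00% ± 5.06 in the controls) and 1 whose nearest gene is Il21, 17365 bp away (0.531% ± 0.0634, 3.73% ± 3.37). Both Tet3_cKO libraries lay below both controls in 27 of the 49 windows that fell. In 46 of the 49, control replicate 1 stood over 2 times as high as control replicate 2, with medians of 6.60% and 1.45%, and 17 of the 49 had over 3 times the median coverage. Without control replicate 1 no window passed (0 of 461613 with the limma-squeezed dispersion; 22391 at an unadjusted p under 0.05), without control replicate 2 the count was 157027, and without either Tet3_cKO replicate it was 16. With the same simulated constant shifts, the recovery in windows changed 3 times was 2.5%. Few simulated windows were called at all, and the 5 unchanged ones among them made 45.5%.

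The fourth comparison asked whether genes of particular blood lineages or functions moved together, with 18 lists fixed before the data were examined. Genes of the T and NK lineage stood highest relative to all genes: the median log2 odds change of its 22 measured members was 0.38 above that of all genes, whose own median was -0.38. The list passed limma camera (preset correlation, adjusted p = 0.000675), and the adjusted p was 0.972 with an estimated correlation. The mean level of the list was 2.31% in control replicate 1, 1.67% in control replicate 2 and 1.88% and 2.25% in the Tet3_cKO libraries. No single member passed, either over all genes or adjusted over the list alone (0 of 22 both ways in the quasi-binomial model with limma-squeezed dispersion). Both Tet3_cKO libraries lay above both controls in 2 of the 22 and below both in 2. Among members with the Tet3_cKO libraries above, Thy1, a T cell surface protein gene, stood at 3.43% and 3.47% in Tet3_cKO and 2.92% and 2.10% in the controls, and Tbx21, a transcription factor of NK and helper T cells, at 2.22% and 2.16% against 2.03% and 1.53%. With an additive background removed, 7 of the 22 passed as higher adjusted over the list alone (0 over all genes). Among them were Tbx21, Bcl11b, Gata3 and Cd3g. In that fit 2 of 20 megakaryocyte genes also passed as higher over their list. So did 1 each in the neutrophil and granule, erythroid, imprinted and housekeeping lists. With library centring 5 of the 22 passed as higher adjusted over the list alone, beside 7 of 21 progenitor transcription factors, 3 of 20 megakaryocyte and 2 of 20 neutrophil and granule genes.

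The stem cell, neutrophil and granule, and megakaryocyte lists also stood above all genes as measured, each with a camera adjusted p = 0.0330 by limma. With an estimated correlation none passed (adjusted p = 0.972 with an estimated correlation for each). As measured, their medians were 0.19, 0.23 and 0.18 above that of all genes. In that fit no member of the 24, 20 and 20 measured passed over all genes or adjusted over the list alone. With an additive background removed, the change was above 0 in 20, 12 and 16 of these members and below 0 in 4, 8 and 4. The median change of all gene bodies was then 0.0146. As measured, the mean levels of these lists in control replicate 1 were 2.13%, 3.45% and 2.71%, and in control replicate 2 1.70%, 2.82% and 1.94%. The number of lists that passed was 3 without control replicate 1, 10 without control replicate 2, 4 without Tet3_cKO replicate 1 and 1 without Tet3_cKO replicate 2. Among stem cell genes Procr, an endothelial protein C receptor gene, stood at 1.27% and 1.69% in Tet3_cKO and 2.18% and 2.23% in the controls, while Txnip stood at 2.04% and 2.14% against 1.22% and 1.77%. Among granule genes the protease gene Prtn3 stood at 4.36% and 3.20% in Tet3_cKO and 1.87% and 2.56% in the controls. Among megakaryocyte genes the platelet glycoprotein gene Gp1ba stood at 2.72% and 2.65% against 4.44% and 4.09%.

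The other 14 lists did not pass as measured. Their camera adjusted p by limma was 0.0633 for the basophil and mast cell list and for the cell cycle list, 0.0749 for progenitor transcription factors, for interferon and inflammation and for housekeeping genes, 0.0782 for endothelial, 0.152 for dendritic, 0.162 for erythroid, 0.294 for TET and DNMT enzymes, 0.435 for monocyte and macrophage and for imprinted, 0.782 for marrow stroma, 0.914 for B lineage and 0.964 for homeobox clusters. As measured, not a single member of these lists passed over all genes or adjusted over the list alone. The monocyte and macrophage median lay 0.11 above that of all genes as measured and turned to -0.14 with an additive background removed, where the list passed as lower and its mean levels as measured were 4.05% and 3.43% in the controls and 3.08% and 3.12% in Tet3_cKO (limma camera adjusted p = 0.0319; adjusted p = 0.786 with an estimated correlation). In that fit the coagulation factor gene F13a1 and the transcription factor gene Zeb2 passed as lower adjusted over the list alone (0 over all genes). F13a1 stood at 2.35% and 2.44% in Tet3_cKO and 4.30% and 3.16% in the controls, and Zeb2 at 3.32% and 3.52% against 4.95% and 4.06%.

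**Figure D3:**
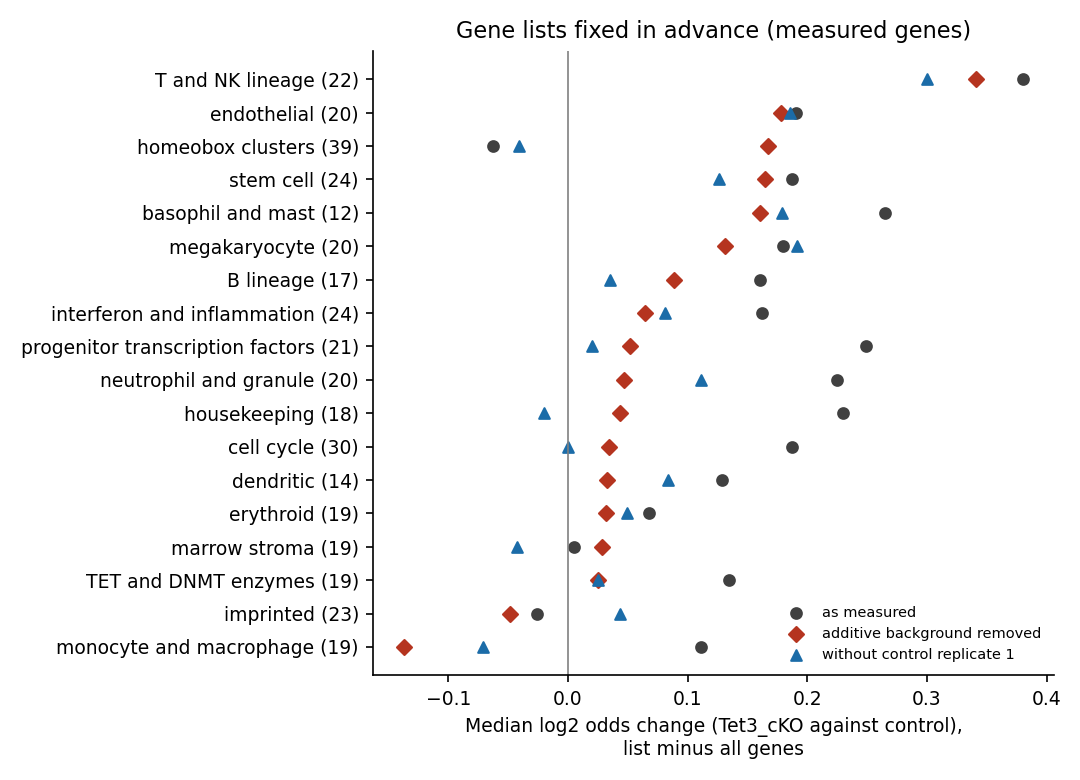
Median log2 odds change of each list (Tet3_cKO against control) minus that of all genes, with the number of measured genes in brackets, in 3 fits: as measured, with an additive background removed, and without control replicate 1. The T and NK list has the highest median in each (0.38, 0.34 and 0.30), and the monocyte and macrophage list turns from 0.11 to -0.14 with the background removed.

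Control replicate 1 lay above control replicate 2 by 0.728 to 0.868 points across windows of under 8%. In windows where the Tet3_cKO libraries averaged under 0.5%, it stood at 1.28% against 0.510%, a ratio of 2.50. In windows of 4% to 8%, it stood at 5.19% against 4.32%, a ratio of 1.20. In the 70 windows of 8% or more, it stood at 11.3% against 8.66%.

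**Figure D4:**
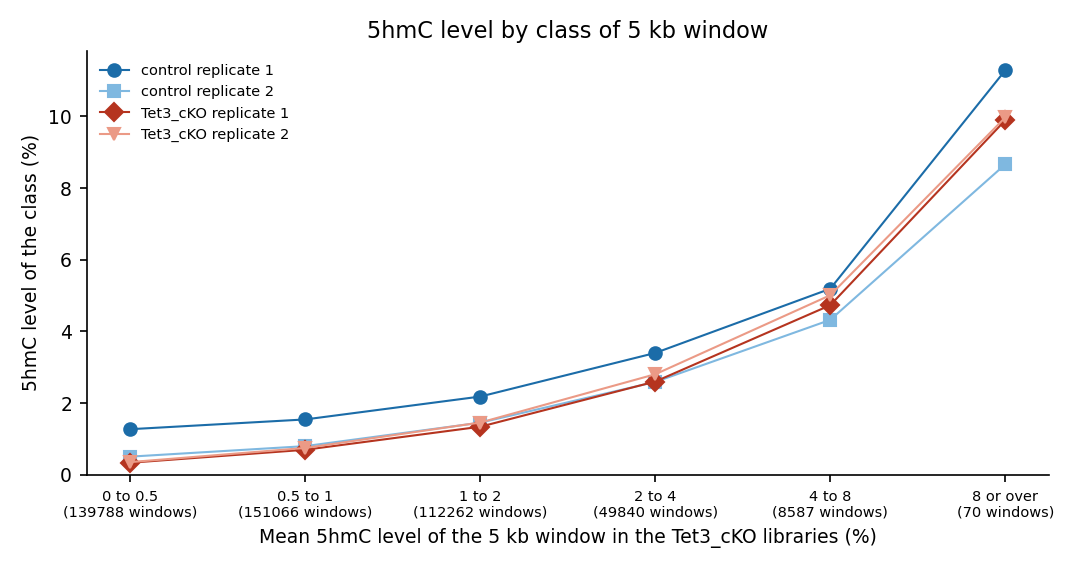
5hmC level (percent) of the 5 kb windows in 6 classes ranked by the mean level of the Tet3_cKO libraries, 1 line per library, with the number of windows under each class. Control replicate 1 exceeds control replicate 2 by 0.765 percentage points in the lowest class and by 0.868 points in windows of 4% to 8%.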

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

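The tests of control replicate 1, the held-out libraries, the splits, the simulated background and, for the T and NK list, the fit without control replicate 1 and all comparisons between lists were chosen after the result was seen.

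The level on chromosome Y, which entered no comparison, was 1.60% in Tet3_cKO replicate 2, above the 1.34% of control replicate 1. It rested on 168673 calls at a mean coverage of 0.354, against 5.07 in control replicate 1; Tet3_cKO replicate 1 stood at 0.477% at a coverage of 5.35. Coverage of chromosome X was 43.1 in Tet3_cKO replicate 2 and 22.6 in the other 2 libraries with values there. The labels do not state sex, but coverage of X and Y reads as female in Tet3_cKO replicate 2 and male in those 2. The Tet3_cKO mice thus probably differ in sex, and the sex of control replicate 2 cannot be read. The 1.60% may then come from misplaced reads and not from chromosome Y.

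Control replicate 1 read higher than the other 3 libraries. An equal share of every cytosine left unconverted is argued against as the whole cause. The excess over control replicate 2 in CpG-dense bins was 0.281 times that in sparse bins. Control replicate 1 also read higher on the mitochondrial chromosome (0.486%, against 0.267% and 0.261% in the Tet3_cKO libraries), so a smaller equal share stays possible. Proportionally more 5hmC is argued against as the whole cause. The ratio of control replicate 1 to control replicate 2 fell 1.92 times from the lowest windows to the highest class, which holds 70 windows. A proportional part beside an added excess stays possible. The excess was 0.868 points in windows of 4% to 8% and 2.62 points in the highest class. Uneven coverage was measured in this library (11.2% of CpGs with over 90% of calls on 1 strand) but is argued against as the whole cause, since at 980016 evenly covered CpGs the excess was still 0.805 points. An incomplete conversion that spares CpG-dense DNA may remain, but no test here decides it.

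With library centring, 3043 windows were called higher in Tet3_cKO and 704 lower, and the total of 3747 became 1 without control replicate 1, 4855 without control replicate 2, and 133 and 61 without Tet3_cKO replicate 1 and 2; of the 3 splits of the 4 libraries only 1, the real one, called as many (at most 58 in the others), and 3 splits are too few for a share under 0.05. Sequence variants between the mice are left open: 97.7% remained without the sites marked CpGx, but the meaning of this mark is not stated in the labels and only 19.9% of these windows hold such a site. A background that is added and not multiplied could contribute: additive centring by limma called 0 windows higher, where limma with library centring called only 27, and with the background removed the median change of these windows fell from 0.94 to 0.67 (median standard error 0.22 and 0.24) and 44 windows were called higher. A simulated background that is even within each CpG density class, with no change, gave 0 windows called of 461613 with library centring, but a background that varies between windows was not simulated, so this stays open. With the background removed, of 1000 windows picked as higher in 1 pair of libraries, 58.8% to 79.1% were higher in the unused pair (44.8% to 48.6% of other windows at the same level; 41.7% to 62.2% of those picked as lower), beside 36.2% to 70% for pairs within genotypes (45.7% to 57.1% of other windows), so the held-out libraries do not settle it.

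T and NK lineage genes stood higher in Tet3_cKO relative to all genes. The background of control replicate 1 is argued against as the whole cause, since without that library, with library centring, the median was 0.30 above that of all genes (limma camera adjusted p = 3.89e-06; adjusted p = 0.843 with an estimated correlation). A lower share of the main cell type that raises every other type alike could contribute: with library centring the list exceeded the B lineage list by 0.231 and the monocyte list by 0.191 (permutation of members), and over 11 cell type lists it exceeded 7 (adjusted p = 0.0315 for the B, monocyte, dendritic, erythroid and endothelial lists, 0.0394 for megakaryocyte and 0.00407 for marrow stroma) but not the stem cell (adjusted p = 0.0850), progenitor (0.128), basophil and mast (0.204) or neutrophil lists (0.245), with genes treated as independent. A second T and NK list with no shared member stood 0.329 above all genes with library centring (31 genes, limma camera adjusted p = 1.07e-07; p = 0.266 with an estimated correlation), and in a permutation of members it exceeded the second neutrophil and monocyte list (adjusted p = 0.0277) but not the second B or the second erythroid and megakaryocyte list (adjusted p = 0.122 each). More T or NK cells, or more 5hmC in them, in the Tet3_cKO libraries could also give these values, which is a hypothesis only. Lineage depletion may have removed T and NK cells, and how far it did so was not measured here. Other lists rose with centring too, and the first list did not pass limma camera with an estimated correlation (p = 0.149).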

How the results depend on the processing

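The separate fits with centring or background removal, background removal itself, additive centring, the CpGx setting and gene ends were chosen after the data were seen; causes of the shifts below were not tested unless given. All 8 level differences stayed below 0 in the 88 alternatives run. The classes overlap, and only the fit without control replicate 1 drops that library. There Tet3_cKO replicate 2 exceeded control replicate 2 in other genes (1.22% against 1.20%) and at gene ends (1.149% against 1.141%). It also did so in bins of 11 to 30 CpGs per kb (1.48% against 1.47%), and lay below in the other classes. Leaving out each library in turn gave -0.848 to -0.0447 points genome-wide, -0.803 to -0.0549 in gene bodies, -0.801 to -0.0173 in other genes, -0.889 to -0.0390 outside genes, -0.329 to -0.0334 at gene ends, and -0.969 to -0.0513, -0.811 to -0.0377 and -0.281 to -0.0228 from sparse to dense bins; the ends of each range are the fits without control replicate 2 and 1. Minus the mitochondrial level, which leaves control replicate 1 as the only control, gene ends gave -0.108 and bins of over 30 CpGs per kb -0.0599, beside -0.329 and -0.281 without control replicate 2 alone; the other 6 differences lay between -0.748 and -0.580.

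Gene bodies past the threshold (2) became 0 with library centring (1997 at an unadjusted p under 0.05), 0 with additive centring by limma (1053), 0 with the background removed (1722), 182 with centring and the replicate block, 17 by limma, 4 with no minimum and 1 with 5 times the minimum; left-out libraries gave 0 to 13342, with centring 0 to 5890 and with the background removed 0 to 1994. Gene ends (15) became 31 with centring, 48 with centring without CpGx sites, 6 with the replicate block, 0 with both block and centring, 0 by limma (3255 at an unadjusted p under 0.05), 0 by edgeR (2823) and 1 with the background removed; left-out libraries gave 0 to 3, with centring 0 and with the background removed 0 to 1056. Windows (50) became 3747 with centring, 258 with the replicate block, 1237 with both, 168 by limma, 0 with additive centring by limma (26422 at an unadjusted p under 0.05), 99 with the background removed, 727 with no minimum, 209 at 2 kb, 14 at 10 kb and 26 without windows over 3 times the median coverage; left-out libraries gave 0 to 157027, with centring 1 to 4855 and with the background removed 18 to 22237. In each case of over 1000 calls, control replicate 2 was the library left out or centring was used. A left-out library leaves 1 in its group, which is assumed to vary like the other.

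The 4 lists past the threshold became 9 with centring, 10 with centring and the replicate block and 0 with an estimated correlation (also 0 with centring and with the background removed); left-out libraries gave 1 to 10, with centring 1 to 10 and with the background removed 1 to 5. The T and NK list passed in every fit with the preset correlation and had an adjusted p of 0.972 with an estimated one. The Tet3 ratio was 0.00394 to 0.0227 with left-out libraries, set by the few calls in each Tet3_cKO library. Of 1990 alternatives for 93 named regions, 1584 gave the same call, 129 added a call, 35 ended one, 242 changed the sign of a region not called as measured and 0 turned a called direction. Promoters past the threshold were not run, since strand is missing from the gene table. Whether libraries were paired by replicate number was not settled. Deviations within genotypes correlated at only 0.0274 across windows, which are not independent, so a shared batch is not excluded. The replicate block raised called windows from 50 to 258 and, with centring, gene bodies from 0 to 182. It lowered gene ends from 15 to 6 and, with centring, windows from 3747 to 1237.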

Other observations

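The search for uncovered runs and the fits with centring or background removal reported here were chosen after the data were seen. With library centring, 31 gene ends were called, each higher in both Tet3_cKO libraries than in both controls, with log2 odds changes from 1.21 to 4.51. Among them were ends of Il18r1 and Il1rl1, receptors of the interleukin 1 family, the TNF family genes Tnfsf4, Tnfsf13 and Tnfrsf14, the cytokine genes Osm and Ccl3, Stat5a and Stat5b, transducers of cytokine signals, and Grxcr1, Bcas1, Ccdc97 and the coagulation factor gene F10. These genes were named after their values were seen, and no enrichment was tested. Without control replicate 1 the centred change stayed above 0 in all 31, but that was given in advance and lends no support. At each of these ends both Tet3_cKO libraries exceeded control replicate 2, and their centring offsets were no higher than that of control replicate 2. With the background removed 1 of the 31 was called, and centring with the replicate block called 0 of 38450 (limma-squeezed dispersion; 3065 at an unadjusted p under 0.05).

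With an additive background removed, which sets the libraries to the same overall level, 44 windows were called higher and 55 lower. In 42 of the 44 both Tet3_cKO libraries lay above both controls, with median levels of 4.06% and 4.21% against 2.18% and 1.97%. Another split of the libraries called 73 windows in the same fit, so these counts say little of genotype.

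The coverage criterion that found the Tet3 segment held for 30 runs of CpGs low in both Tet3_cKO libraries, 28 of them on chromosome 10 between 81677425 and 82779953. It held for 546 runs low in both controls, 539 of them on chromosome 13 between 40545827 and 108585969; of the 3 on chromosome 18, 1 lies past the last position covered in control replicate 2. It held for 242 runs low in control replicate 1 and Tet3_cKO replicate 2, 240 of them on chromosome 3 between 77597385 and 128697655. On chromosome 13, 0 of 13355 windows in that span passed as measured and 119 were called higher with centring. Over all windows centring called 3043 of 461613 higher, and in the chromosome 3 span 74 of 10061. In the chromosome 3 span, which holds H3c13, 2 of 10061 windows passed as measured, against 50 of 461613 over all windows.

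Coverage of chromosome X was 22.6 in control replicate 1 and in Tet3_cKO replicate 1, and 43.1 in Tet3_cKO replicate 2. The level on chromosome X was 1.83%, 0.882% and 0.701%, and on the mitochondrial chromosome 0.486%, 0.267% and 0.261%, in the same order. On chromosome 19 it was 2.17%, 1.30% and 1.39%.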
